A study of Drosophila melanogaster with 3 samples.

How the data were processed

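The series holds 3 samples of embryonic Drosophila melanogaster cells of genotype twi(2xPE)>mCD8GFP, labelled stage 5 to 10. Per the design text, eggs were laid over 1.5 h and the embryos aged for 3 h and 15 min at 22 °C. Per the labels' protocols, cells were freed by douncing and Accumax treatment, filtered, depleted of dead cells, and made into 3' libraries with version 3 of the 10x Chromium chemistry, with methanol fixation for sample 3. The authors deposited a filtered matrix of whole-number UMI counts per gene and barcode, made with Cell Ranger on genome build dm6 per the submitters' processing notes. The aligner's version, the annotation, the use of intronic reads and of strand, and any removal of free RNA or doublets are not given in the sources used here. The count matrices of wild-type 1 and fixed wild-type 3 were used (2 matrices). That of live wild-type 2, with 15834 barcodes, was not analysed here. No label says that the libraries came from separate egg collections. The label of wild-type 1 does not carry the word live, and its lack of fixation is taken from the design text.

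The count table lists 17139 genes, of which 16293 matched the Ensembl annotation of BDGP6.54 (release 115, the same assembly as dm6) by symbol. The annotation served for coordinates only. The count table holds 0 mitochondrial genes, so a planned limit of 10% mitochondrial UMIs could not be applied. Barcodes with at least 1000 UMIs and 500 genes were kept (9437 and 13083). Doublets were scored per library as the share of simulated doublets, 2 per cell, among each cell's neighbours. The threshold was the valley between the modes of the simulated scores, and 375 (3.97%) and 561 (4.29%) cells were left out. Each library was clustered by itself on 1500 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1. All genes of the gene lists and the transgenes were left out of the clustering.

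Clusters were named X-like from marker genes of 13 classes. A name required a mean marker log2 ratio of at least 1 over the median cluster (pseudocount 10 CPM), at least 3 markers raised 2-fold, and a margin of 0.5 over the next class. It also required that the 10 leading genes by fold, among those with at least 30 CPM, did not hold as many markers of another class. Clusters with few UMIs and no leading marker stayed unnamed, as did clusters led by the muscle myosin gene Mhc, the fat body gene apolpp or the cuticle gene Osi6, a rule added after the clusters were seen. Ectoderm-like joins the neurogenic and dorsal ectoderm classes. The markers and lists were set before the data were examined, as were the tests, the gates, the rule for named genes and the alternatives not listed as added. The scoring rule for names was set after.

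UMI counts were summed per library and class of cells, and these sums were tested, since cells are not replicates. The main test was edgeR's quasi-likelihood test with TMM scaling, filterByExpr, the library as a block and Benjamini-Hochberg adjustment at 0.05. Mesoderm against ectoderm was tested on genes other than the 1900 used as clustering features. A single fit over layer, Hox bin and library gave the posterior-against-anterior contrasts and their interaction, with 7 residual degrees of freedom. The other 2 fits had 1. Hox bins were set by the largest of the UMI sums of Dfd and Scr, Antp, Ubx and abd-A, or Abd-B, leaving out ties, and every bin used held at least 20 cells per library. The early gate took mesoderm-like cells with at least 2 UMIs over nullo, bnk, halo and slam (Sry-alpha had 0 UMIs) against cells with 0, leaving out 307 and 556 cells with 1. Gate genes were not tested in the contrasts they set. Fold bounds against a side with 0 counts used a floor of 3 counts over that side.

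Gene lists (19) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, and with fry. They were Hox, gap and head gap, pair-rule, segment polarity, head and trunk regulators, mesoderm subdivision and muscle, FGF, Notch with Enhancer of split and Bearded complexes, tissue folding, cellularisation, cell division, BMP, EGF receptor, Wnt, JAK/STAT, patterned cell surface receptors, heat shock and stress, maternal regulators, and dosage compensation. Named genes were the 12 with the largest log2 difference in each direction among those past 0.05, with the same sign in both libraries and at least 50 UMIs in each, and up to 4 members per list with the smallest p. For the fixed against the unfixed library they were the 10 largest CPM ratios each way among genes with at least 50 CPM in a library, over all cells and in mesoderm-like cells. For that pair no test was made. CPM ratios carry exact Poisson-based 95% intervals, shares carry exact binomial ones, and lists carry the percentile of their median among 10000 random lists matched over 20 expression bins. All these intervals cover counting error only.

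The steps were tested on simulated counts with 200 changed genes per contrast. Of genes changed by a log2 of 0.5, 1 and 2, the layer contrast recovered 70.8, 85.1 and 98.4%, with 6 false calls among 8561 unchanged genes. The mesoderm contrast recovered 52.2, 87.3 and 97.0% (15 of 7678 false), the ectoderm contrast 64.1, 86.4 and 98.5% (9 of 7684), the interaction 28.1, 60.3 and 87.7% (3 of 7687) and the early contrast 53.1, 66.7 and 80.7% (5 of 9057). A simulated raised list was called in each contrast, and 0 of 9 unchanged lists were. The simulated genes were independent and shared the common spread of each fit. These rates therefore do not cover spread that differs between genes or correlation within lists.

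Alternatives were DESeq2's size factors in the edgeR test, DESeq2's Wald test, no filter on low counts, no library block, doublets kept, cells thinned to 3000 UMIs (leaving out 693 and 1814 shallower cells), Leiden resolution 2, each library left out, stricter or wider gates, an estimated correlation, all barcodes, and other scalings of the library comparison. Alternatives chosen after seeing the data were a wider mesoderm class, leaving out clusters led by sna or SNCF, leaving out clusters of few UMIs, and, for the library comparison, leaving out clusters led by Mhc or TpnC73F. Depth per gene limits rare transcripts: genes of a few UMIs per class have wide errors. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.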

Results

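Single-cell RNA profiles were collected from whole embryos of the fruit fly Drosophila melanogaster at stages 5 to 10, the period from cell formation through gastrulation to the extended germ band. The embryos carried a membrane-bound green fluorescent protein (mCD8GFP) driven through a twist enhancer. Of the 3 samples, wild-type 1 was processed without fixation per the design text, live wild-type 2 was not analysed here, and fixed wild-type 3 was fixed in methanol. The matrix of wild-type 1 held 9845 barcodes and 170489040 UMIs (unique molecular identifiers, counted transcript molecules), with a median of 15252 UMIs and 2910 genes per barcode and a range of 501 to 377447 UMIs. That of the fixed library held 13142 barcodes and 305562463 UMIs, with a median of 21070 UMIs and 3208 genes and a range of 526 to 638206 UMIs. After filters and removal of called doublets, 9062 and 12522 cells were used. Tests compared UMI counts summed per class of cells within each library, with the library as a block. Every p-value of the main tests therefore measures how class differences vary across only these 2 libraries, which also differ in fixation. The 7 residual degrees of freedom of the fit over layer and Hox bin come from several class sums of the same 2 libraries. The fit of the layers had 1, so its p-values rest largely on spread shared between genes. Values with ± are log2 differences with their standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gave every adjusted p of a gene (n = 2 libraries). In pairs of log2 differences given by library, the value in wild-type 1 comes first and that in the fixed library second. Coordinates are those of the BDGP6.54 annotation.

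Clustering each library separately gave 26 clusters in wild-type 1 and 24 in the fixed library, of which 12 and 13 could be named from marker genes. Mesoderm-like cells carried twi, the basic helix-loop-helix determinant of mesoderm, and Mef2, a muscle transcription factor. They accounted for 31.9% of wild-type 1 (2895 cells, exact 95% interval 31.0 to 32.9%). They made up 27.7% of the fixed library (3474 cells, 27.0 to 28.5%). Neurogenic and dorsal ectoderm-like cells, marked by genes such as sog, an antagonist of BMP signalling, made up 13.5% (1225 cells, 12.8 to 14.2%) and 19.0% (2382 cells, 18.3 to 19.7%). In the mesoderm-like cells twi stood at 587.6 CPM (counts scaled to a common library total) in wild-type 1 and 387.6 CPM in the fixed library. It stood at 14.2 and 15.1 CPM in ectoderm-like and 22.2 and 34.5 CPM in pole cell-like cells. Mef2 stood at 534.5 and 547.9 CPM in mesoderm-like and 16.6 and 21.9 CPM in ectoderm-like cells. The gene sog stood at 414.1 and 518.1 CPM in ectoderm-like and 23.4 and 28.0 CPM in mesoderm-like cells. Pole cell-like cells, the germ line precursors, made up 3.95 and 4.19% and carried pgc, a germ line repressor of transcription, at 3139 and 2031 CPM. Head mesoderm and blood-like cells made up 4.59 and 3.07% and carried the glial and blood cell factor gcm at 574.4 and 379.3 CPM, against 2.10 and 1.21 CPM in mesoderm-like cells. Neuroblast-like cells made up 2.40 and 1.45%, and head ectoderm-like cells 3.34 and 6.39%. No cluster was named dorsal ectoderm-like in wild-type 1 (0 of 9062 cells, exact upper bound 0.041%), against 5.02% in the fixed library. That 0 belongs to this clustering alone: wild-type 1 held 4.73% dorsal ectoderm-like cells at resolution 2, 4.59% with doublets kept and 4.41% with all barcodes. In this clustering no cluster of either library met the rule for endoderm, hindgut, mesectoderm, amnioserosa, tracheal primordium or yolk nuclei, which does not show that such cells were absent. Clustering all barcodes gave 1 tracheal primordium-like cluster in wild-type 1 (105 cells, 1.07%). Unnamed clusters with fkh and CG2930 among their 10 leading genes held 287 and 206 cells in wild-type 1 and 505 and 329 cells in the fixed library. Unnamed clusters with peb, Ance and tup there held 115 and 214 cells. A cluster of 163 cells in wild-type 1 led by the cuticle gene Osi6 stayed unnamed as well. Among the neurogenic ectoderm-like cells of the fixed library, a cluster of 79 cells was led by rho, sog and the midline gene sim. Unnamed clusters held 40.3 and 38.1% of cells, among them clusters with mesoderm markers raised at least 2-fold (467 cells, 5.15%, and 556 cells, 4.44%). The mesoderm-like class did not hold matching clusters in both libraries. In wild-type 1 it included a cluster of 382 cells led by jeb and Poxm and one of 100 cells led by Alk, org-1, bap and bin, genes of the visceral mesoderm. A cluster of 1289 cells led by jeb and org-1 stayed unnamed in the fixed library. With 1 library of each kind these shares have no replicate check, and their intervals cover counting error only. Clustering with called doublets kept gave mesoderm-like shares of 22.9 and 26.6%.

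**Figure D1:**
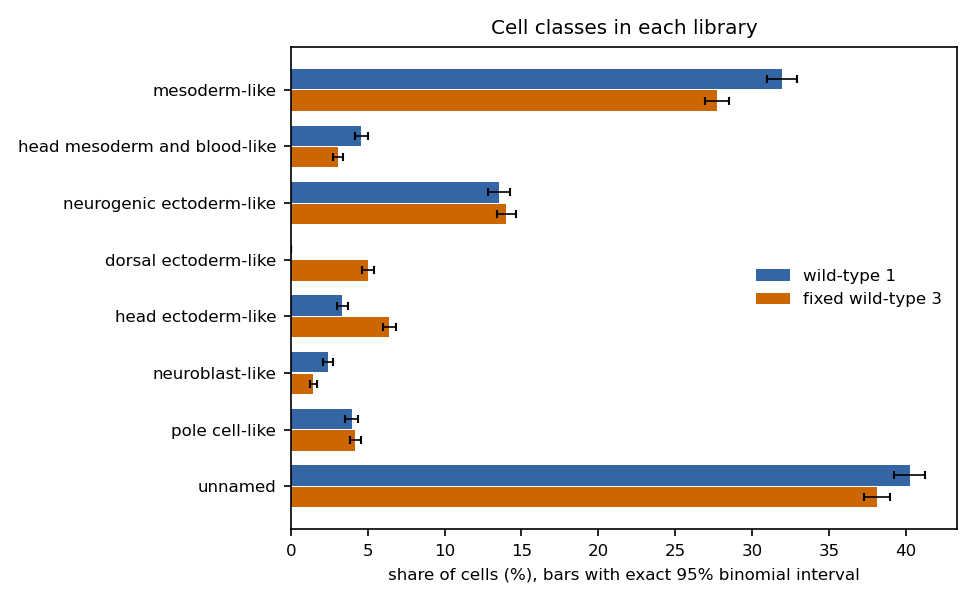
Share of cells (percent, horizontal axis) in each class for wild-type 1 (blue) and fixed wild-type 3 (orange), with exact 95% binomial intervals as error bars. Mesoderm-like cells held 31.9 and 27.7%, and unnamed clusters 40.3 and 38.1%.

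The mesoderm was compared with the ectoderm to describe what separates these germ layers, leaving out the genes on which the clusters rested. Mesoderm-like cells carried more htl, the FGF receptor of the mesoderm (FBgn0010389, chromosome 3R, 18045216 to 18052984, minus strand; 5.45 ± 0.07, adjusted p = 4.86e-14), and more of its adaptor stumps (5.30 ± 0.10). They also carried more of the N-cadherin gene CadN (5.18 ± 0.04, adjusted p = 4.23e-16) and of bap, a homeobox gene of visceral muscle (5.21 ± 0.15). Him, an inhibitor of muscle differentiation, was higher as well (4.75 ± 0.18, adjusted p = 8.17e-10). Ectoderm-like cells carried more Cad99C, a protocadherin of apical microvilli (-5.60 ± 0.16, adjusted p = 3.84e-11), and more of the FGF ligand genes ths (-5.28 ± 0.13) and pyr (-4.32), whose products act on the Htl receptor. The E-cadherin gene shg was also higher in ectoderm-like cells (FBgn0003391, chromosome 2R, 21049654 to 21057197, minus strand; -1.85 ± 0.04). Of 8670 genes tested, 3624 passed an adjusted p of 0.05, 1960 higher and 1664 lower in mesoderm-like cells, and 779 differed at least 2-fold. Both libraries gave the same sign for 3614 of the 3624. DESeq2 called 1878 (929 higher and 949 lower), edgeR without the library block 81 (22 and 59), and edgeR on cells thinned to 3000 UMIs 1383 (609 and 774), so the balance turned in these 3. Because the classes were named from marker genes, the differences of htl, stumps, ths, vn and dpp are not independent of the naming.

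Further genes higher in ectoderm-like cells were grnd, a tumour necrosis factor receptor (-5.27 ± 0.14), tld, a protease that releases BMP ligands (-4.95), and the BMP-binding gene cv-2 (-4.12). The ligand genes Wnt2 (-4.86), upd2 (-4.54) and dpp (-4.32) were on this side too, with the limb homeobox gene Dll (-4.66 ± 0.15), veil (-4.71) and the neprilysin-like gene Nepl12 (-4.45). Skeletor was higher in mesoderm-like cells (4.77 ± 0.20). Both transgene transcripts, named here after their values were seen, were higher in mesoderm-like cells: mCD8GFP by 1.59 ± 0.08 (adjusted p = 7.75e-09) and its driver GAL4 by 3.87 ± 0.24 (adjusted p = 7.93e-08). The level of mCD8GFP was 110.5 and 186.9 CPM in mesoderm-like, 29.7 and 68.7 CPM in ectoderm-like and 1.42 and 5.88 CPM in pole cell-like cells of wild-type 1 and the fixed library.

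Patterning genes of the embryonic axes were mostly lower in mesoderm-like cells. Of 8 Hox genes 1 was higher, 6 were lower and 1 did not pass (7 adjusted over the list alone). Antp was at -1.73, Scr at -1.62 and lab at -2.92, while Ubx was higher (0.36; by library 0.49 and 0.23). Of 13 gap and head gap genes 0 were higher and 11 lower (11 adjusted over the list alone). Among them were the POU genes nub (-2.94) and pdm2 (-3.15), the head homeobox gene oc (-3.42) and hb (-1.62). All 9 pair-rule genes, the stripe-forming transcription factors, were lower (9 adjusted over the list alone), for example run (-0.85), h (-0.72) and odd (-0.75). All 11 segment polarity genes were lower (11 adjusted over the list alone), for example hh (-0.97), en (-1.20) and inv (-1.39). Of 9 head and trunk regulators 0 were higher, 5 were lower and 4 did not pass (5 adjusted over the list alone), with disco at -2.82 and salm at -2.48. Camera with a preset correlation called these lists lower, with adjusted p = 6.64e-06 for Hox, 1.93e-25 for gap, 5.54e-06 for pair-rule, 1.35e-10 for segment polarity and 4.9e-10 for head and trunk genes. With an estimated correlation the adjusted p was 0.359 for Hox and 0.332 for each of the other 4. In this fit the estimated version rests on 1 residual degree of freedom. It could call hardly any list, so its values in this contrast do not decide.

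Mesoderm subdivision and muscle genes were higher in 9 of 11 cases, with 1 lower and 1 not passing (10 adjusted over the list alone). Camera called the list higher (adjusted p = 2.14e-13, adjusted p = 0.332 with an estimated correlation). They included the myoblast fusion gene sns (3.05) and the RNA-binding gene how (0.91), and the exception was the homeobox gene lbe (-3.01). Cell division genes were higher in 8 of 13 cases and lower in 1 (9 adjusted over the list alone; camera adjusted p = 0.00735, adjusted p = 0.332 with an estimated correlation). The mitotic phosphatase gene stg rose by 1.31 and the cyclin genes CycB and CycA by 0.48 and 0.43, while trbl, which delays mitosis in the mesoderm, was lower (-0.78). Among 17 tissue folding genes 5 were higher, 7 lower and 5 did not pass (12 adjusted over the list alone). CadN, the signalling adaptor gene Traf4 (0.82) and fog, a secreted trigger of apical constriction (0.69), were on the higher side. The folding list had a median of -0.03 and a mean of 0.24, and camera called it higher (adjusted p = 0.0327, adjusted p = 0.562 with an estimated correlation). All 3 cellularisation genes tested were lower (3 adjusted over the list alone; camera adjusted p = 0.0102, adjusted p = 0.46 with an estimated correlation), with halo, a regulator of lipid droplet transport, at -3.22. At least 2 UMIs of the cellularisation genes were found in 2.97 and 4.29% of mesoderm-like but 29.1 and 32.2% of ectoderm-like cells. The layer differences, those of the pair-rule genes included, were not adjusted for this.

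Signalling genes were mostly lower in mesoderm-like cells. Of 18 Notch pathway and Enhancer of split or Bearded genes 2 were higher, 14 lower and 2 did not pass (16 adjusted over the list alone). Camera called them lower (adjusted p = 1.14e-26, adjusted p = 0.332 with an estimated correlation). Among them were E(spl)mdelta-HLH (-2.78), E(spl)mgamma-HLH (-2.41) and the ligand gene Dl (-1.10), while E(spl)m6-BFM was higher (2.08). Of 12 BMP genes 3 were higher and 7 lower (10 adjusted over the list alone; camera adjusted p = 2.92e-16, but 0.332 with an estimated correlation). Of 8 EGF receptor genes 2 were higher and 5 lower (7 alone; 7.94e-05, but 0.332 with an estimated correlation). Of 11 Wnt genes 1 was higher and 9 lower (10 alone; 6.32e-06, but 0.332 with an estimated correlation). The counts were 1 and 4 of 6 JAK/STAT genes (6 alone; 0.000146) and 1 and 7 of 8 patterned cell surface receptor genes (8 alone; 7.51e-13), but 0.332 for each with an estimated correlation. Examples were the EGF-like ligand gene vn (-3.50), the ETS factor gene pnt (0.82) and the cytokine gene upd1 (-3.52). Others were the Wnt deacylase gene Notum (-1.47), Wnt6 (1.19) and the Toll-family genes Tollo (-2.49) and Toll-6 (-1.16). Of 9 FGF genes 3 were higher and 4 lower (7 adjusted over the list alone). Their median of -0.10 and mean of -0.06 lay opposite to camera's direction, which did not pass (adjusted p = 0.598). Of 16 heat shock and stress genes 1 was higher, Hsp70Bb (1.14), and 8 were lower (9 adjusted over the list alone), such as the AP-1 gene kay (-2.14) and the chaperone gene Hsp83 (-0.60). Camera called the list lower (adjusted p = 0.0263, adjusted p = 0.357 with an estimated correlation). Of 11 maternal regulators 2 were higher, such as plu (0.80), and 1 was lower, brat (-0.36) (3 adjusted over the list alone). That list did not pass camera (adjusted p = 0.917), with a median of -0.14 and a mean of 0.06. Of 7 dosage compensation genes 4 were higher and 2 lower (6 adjusted over the list alone; camera adjusted p = 0.317), with the noncoding RNA genes lncRNA:roX2 at 0.81 and lncRNA:roX1 at -0.43. Camera with the preset correlation called 16 of the 19 lists. With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.332. With 1 residual degree of freedom that version could call hardly any list, so the 0 does not decide. Fry, which tests whether a list's genes move one way on balance, called 4, and its mixed test, for change in either direction, called 14.

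To place cells along the anterior-posterior axis, the question of this study, each cell was assigned to the Hox group with most UMIs: gnathal (Dfd, Scr), thoracic (Antp), abdominal (Ubx, abd-A) or terminal (Abd-B). These sums are raw, and the gnathal and abdominal ones take more genes than the thoracic and terminal ones. Shares therefore follow the level of each Hox gene in a layer as well as position. Antp was lower and Ubx higher in mesoderm-like than in ectoderm-like cells, which favours abdominal assignment there. Cells assigned as abdominal dominated the mesoderm-like class, with 62.5% in wild-type 1 (1808 cells, exact 95% interval 60.7 to 64.2%) and 61.5% in the fixed library (2137 cells, 59.9 to 63.1%). Thoracic cells held 16.7 and 18.9%, terminal cells 7.88 and 6.91% and gnathal cells 5.29 and 5.27%. Ectoderm-like cells were thoracic in 38.1 and 40.9%, abdominal in 22.9 and 27.2%, terminal in 13.1 and 9.36% and gnathal in 9.06 and 8.86%. Any assignment was possible for 92.3 and 92.6% of mesoderm-like and 83.2 and 86.4% of ectoderm-like cells, at median depths of 21474 and 24891.5 UMIs and 18934 and 23001.5 UMIs. Pole cell-like cells, which should lack Hox expression, were assigned in 57.0 and 57.1% at 18372.5 and 21858 UMIs. Their shares were 0.559 and 1.34% gnathal, 18.2 and 16.6% thoracic, 25.4 and 24.8% abdominal and 12.8 and 14.3% terminal. Below these pole cell-like shares lay terminal mesoderm in both libraries, terminal ectoderm in the fixed library, and thoracic mesoderm and abdominal ectoderm in wild-type 1. Terminal ectoderm in wild-type 1, and thoracic mesoderm and abdominal ectoderm in the fixed library, lay above them with overlapping intervals, so these bins can hold cells assigned by background UMIs. In CPM, Ubx stood at 410.2 and 429.6 in mesoderm-like against 36.8 and 35.9 in pole cell-like cells, and Dfd at 5.55 and 9.23 against 1.10 and 2.21. Abd-B stood at 71.9 and 84.3 against 48.6 and 37.9, closer to the level of pole cell-like cells. An Abd-B UMI was found in 25.8 and 26.4% of mesoderm-like and in 34.6 and 30.7% of pole cell-like cells. In head ectoderm-like cells Abd-B stood at 6.06 and 11.7 CPM, so pole cell-like cells may overstate its background.

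Posterior mesoderm, the mean of abdominal and terminal cells, was compared with gnathal mesoderm to find genes patterned along this axis in the mesoderm. Terminal cells had the same weight as abdominal ones, though their bin can hold cells assigned by background UMIs. Unnamed clusters with Abd-B and FoxL1 among their 10 leading genes, in both libraries, lay outside the class. Posterior cells carried more of the noncoding RNA gene lncRNA:iab8 of the bithorax complex (FBgn0264857, chromosome 3R, 16831116 to 16923231, minus strand; 5.49 ± 0.25, adjusted p = 2.3e-09). They also carried more of the forkhead factor gene FoxL1 (FBgn0004895, chromosome 3L, 4018878 to 4021279, plus strand; 3.35 ± 0.19, adjusted p = 2.23e-08) and of the muscle actin gene Act87E (2.99 ± 0.15, adjusted p = 3.92e-09). Gnathal cells carried more pb, a Hox gene of the mouthparts (-5.18 ± 0.47, adjusted p = 7.23e-06), and more gt, a gap gene also active in the head (FBgn0001150, chromosome X, 2427113 to 2428967, minus strand; -4.20 ± 0.20, adjusted p = 2.48e-09). Also higher there were salm, a zinc finger gene of head and tail (-3.11 ± 0.21, but -1.59 with a wider mesoderm class), and bnl, the FGF ligand gene of the tracheal system (-2.63 ± 0.11, adjusted p = 9.92e-10). Of 8054 genes tested, 372 passed, 185 higher and 187 lower in posterior cells, with 86 at least 2-fold and the same sign in both libraries for all 372. The bins held different mixes of clusters: in wild-type 1 the largest cluster held 79.1% of gnathal, 69.3% of abdominal and 36.8% of terminal mesoderm-like cells, and the cluster led by Alk and org-1 1.31, 2.77 and 12.3%. In the fixed library the largest cluster held 41.5, 41.4 and 29.2% of these bins. Without the filter on low counts 351 were higher and 193 lower. With every cell thinned to 3000 UMIs 27 passed, without the library block 30, with Antp cells on the anterior side 222 and without clusters led by sna or SNCF 235; the gate genes themselves were not tested.

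Other posterior genes were lncRNA:bxd (4.87 ± 0.32), lncRNA:iab4 (4.83 ± 0.50), lncRNA:CR43617 (3.92 ± 0.47), CG1673 (4.35 ± 0.34) and the planar polarity gene sano (2.88 ± 0.65; by library 4.88 and 2.14). CG31275, whose annotated span lies inside that of lncRNA:bxd on the same strand, had 264 UMIs in posterior and 0 in gnathal cells, at least 7.01-fold higher against a floor of 3 counts over the gnathal group. Over both libraries Ref2 stood at 6.35 CPM in posterior against 0.234 CPM in gnathal cells, IP3K1 at 3.51 against 0.351 CPM and sand at 1.26 against 0.117 CPM, where the gnathal levels rest on 2, 3 and 1 UMIs. Further gnathal genes were the PRDM factor gene ham (-3.87; by library -2.57 and -4.30), the EBF-type factor gene kn (-3.78; by library -1.06 and -4.57) and the zinc finger gene btd (-2.55; by library -1.52 and -3.28). The bHLH-PAS gene ss (-2.36; by library -0.33 and -3.02), stl (-2.10), lncRNA:CR45559 (-4.59) and lncRNA:CR44931 (-3.34) were lower as well. In the bithorax complex (chromosome 3R, 16656623 to 16972236) all 6 tested genes other than the gates were higher in posterior mesoderm. In the Antennapedia complex (chromosome 3R, 6661427 to 6999228) 5 of 16 passed, all lower. Several of these transcripts overlap gate genes or each other, and since strand use in counting is not given in the sources used here, their separate levels are uncertain.

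**Figure D2:**
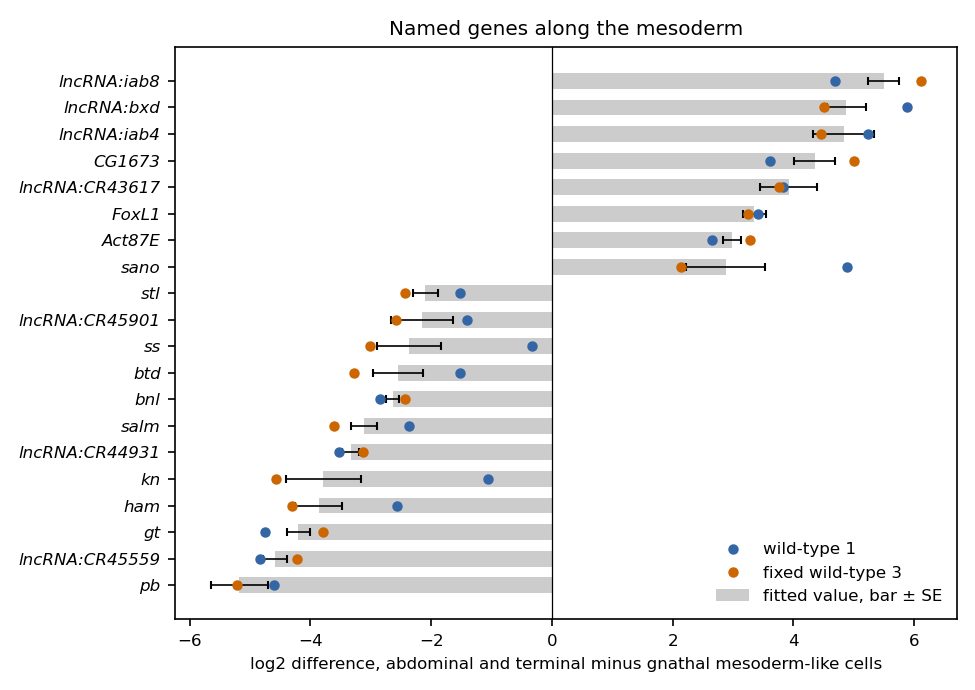
Log2 difference of posterior against gnathal mesoderm-like cells (horizontal axis) for named genes, as the fitted value (grey bar) with its standard error (line) and the value in each library (points). Genes on the posterior side run from sano at 2.88 to lncRNA:iab8 at 5.49, and genes on the gnathal side from stl at -2.10 to pb at -5.18.

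Among the fixed lists, 1 of 13 gap genes was higher in posterior mesoderm, nub (2.27), and 4 were lower (5 adjusted over the list alone). The lower genes were gt, btd, knrl (-2.07; by library -1.31 and -2.36) and kni (-1.44; by library -0.88 and -1.69). The list was lower by camera (adjusted p = 0.0138, adjusted p = 0.591 with an estimated correlation). Of 9 pair-rule genes 3 rose and 2 fell (6 adjusted over the list alone). Risers were opa (0.90), odd (1.06; by library 0.54 and 1.85) and run (0.54; by library 0.27 and 0.84; -0.22 in thinned cells), with slp2 at -0.86 and slp1 at -0.56. Of 10 segment polarity genes 0 rose and 3 fell (4 adjusted over the list alone), namely wg (-0.90), nkd (-0.23) and ptc (-0.19; by library -0.29 and -0.09; 0.026 with a wider mesoderm class). Their median of 0.10 and mean of 0.11 were positive, against camera's downward direction. Of 8 head and trunk regulators tsh, the trunk zinc finger gene, rose (1.82) and 3 fell (4 adjusted over the list alone): salm, hth (-0.70) and exd (-0.24). Their median was 0.29 and their mean -0.02. These 3 lists did not pass camera (adjusted p = 0.242, 0.388 and 0.263). Of 9 FGF genes 3 fell (4 adjusted over the list alone), bnl, htl (-0.33) and the pathway inhibitor gene sty (-0.24). The list was lower (camera adjusted p = 1.45e-05, adjusted p = 0.149 with an estimated correlation). Of 18 Notch genes 2 fell (5 adjusted over the list alone), Dl (-0.24) and E(spl)mgamma-HLH (-0.58; camera adjusted p = 0.0138, adjusted p = 0.591 with an estimated correlation). Of 17 folding genes mthl1, the receptor gene also known as mist, rose (0.59), and fog (-0.68) and Traf4 (-0.38) fell (4 adjusted over the list alone; camera adjusted p = 0.388). Among 11 BMP genes tok rose (1.32; by library 0.85 and 2.03) and dpp fell (-1.20; 3 adjusted over the list alone). Hsp83 was the only 1 of 14 stress genes to fall (-0.78). None of the 9 mesoderm subdivision and muscle genes passed, with 0 over all genes and 0 adjusted over the list alone. Camera called 3 of 17 lists with the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05 and the lowest adjusted p was 0.149. Fry called 1 and its mixed test 13.

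The same contrast in ectoderm-like cells showed more tsh in posterior cells (FBgn0003866, chromosome 2L, 21828593 to 21837011, plus strand; 4.07 ± 0.13, adjusted p = 3.5e-11). Posterior cells also carried more lncRNA:iab8 (5.99 ± 0.24, adjusted p = 3.48e-10) and more of the dorsal GATA factor gene pnr (3.76 ± 0.25). Gnathal ectoderm carried more of the appendage genes Sp1 (-4.71 ± 0.26, adjusted p = 1.21e-08) and Dll (FBgn0000157, chromosome 2R, 24814822 to 24835667, plus strand; -3.89 ± 0.14, adjusted p = 1.37e-10). It also carried more cnc, a bZIP gene of the mandibular segment (-3.30 ± 0.23). Of 8054 genes 455 passed, 222 higher and 233 lower in posterior cells, 156 at least 2-fold and 454 with the same sign in both libraries. With cells thinned to 3000 UMIs 43 passed, and without the library block 78. The ectoderm bins also held different mixes of clusters. In the fixed library the dorsal ectoderm-like cluster, led by dpp and pnr, held 30.3% of gnathal, 27.3% of abdominal and 41.7% of terminal cells. In wild-type 1 a cluster at a median of 3215 UMIs held 11.7, 26.0 and 26.3% of these bins. The contrast does not separate the axis from this mix. Other posterior genes were lncRNA:CR43617 (5.23; by library 7.39 and 4.30), lncRNA:CR44917, which lies next to tsh (4.74), lncRNA:iab4 (4.55) and lncRNA:bxd (4.10). Over both libraries C15 stood at 7.39 CPM in posterior against 0.328 CPM in gnathal cells and sano at 5.35 against 0.218 CPM, on 3 and 2 gnathal UMIs. Other gnathal genes were lncRNA:CR45559 (-4.76), lncRNA:CR44931 (-3.99), gt (-2.61), btd (-2.59), bnl (-2.37), pb (-2.36; by library -0.68 and -3.61) and the metabolic enzyme gene Gpo1 (-2.12). The transgene mCD8GFP, named after its value was seen, was also lower in posterior ectoderm (-0.79 ± 0.19, adjusted p = 0.0213). In the bithorax complex 5 of 6 genes rose and in the Antennapedia complex 2 of 16 rose and 4 fell.

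In the ectoderm 6 of 13 gap genes fell and 1 rose (10 adjusted over the list alone), with knrl at -2.06 and pdm2 at -0.67 (by library -0.94 and -0.44). Of 9 pair-rule genes 3 rose, prd (1.91), eve (1.95) and run (0.65), and slp2 fell (-0.83; 6 adjusted over the list alone). Of 10 segment polarity genes 4 fell and 0 rose (10 adjusted over the list alone), for example inv (-1.11), hh (-0.33; by library -0.21 and -0.41) and ptc (-0.22; 0.022 in thinned cells). Of 8 EGF receptor genes 3 fell (5 adjusted over the list alone), the feedback inhibitor gene kek1 (-1.0; by library -0.55 and -1.34), the ligand-processing gene rho (-0.72) and pnt (-0.38). Camera gave adjusted p = 1.31e-07 for gap, 0.00225 for pair-rule, 6.99e-05 for segment polarity and 0.00149 for EGF receptor genes. With an estimated correlation the adjusted p was 0.0588, 0.0621, 0.0588 and 0.0588. Of 18 Notch genes 3 rose, E(spl)m2-BFM (0.68), Tom (0.41) and E(spl)m8-HLH (0.32), and Dl fell (-0.14; by library -0.08 and -0.19; 9 adjusted over the list alone). Camera called the list higher (adjusted p = 0.0113, adjusted p = 0.316 with an estimated correlation). Of 17 folding genes fog fell (-1.04) and mthl1 rose (0.62; 2 adjusted over the list alone; camera adjusted p = 0.0498, lower, but 0.133 with an estimated correlation). Of 9 FGF genes 1 rose and 2 fell (4 alone; 0.0113), and of 8 receptor genes 0 rose and 2 fell (5 alone; 0.0248), but 0.133 and 0.111 with an estimated correlation. Of 8 head and trunk regulators 1 rose and 4 fell (6 adjusted over the list alone; camera adjusted p = 0.0541), with disco at -1.86. Of 11 BMP genes cv-2 (0.87) and dpp (0.64) rose (2 adjusted over the list alone; camera adjusted p = 0.156), with a median of -0.01 and a mean of 0.13. Among stress genes kay rose (1.09) and Hsp83 fell (-0.83), and lncRNA:roX1 was the only dosage compensation gene to pass (-0.29). Camera called 8 of 17 lists with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05. Fry called 10 and its mixed test 14. Between the layers, 52 genes were higher in the posterior of both and 54 lower in both, where independent lists would share 5.10 and 5.41, and 17 called in both had opposite signs. Both layers came from the same libraries and the same fit, which a count for independent lists leaves out.

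Whether the posterior-against-gnathal difference itself differed between mesoderm and ectoderm was tested as an interaction. Dll was graded in the ectoderm, at 92.2 CPM in gnathal and 6.63 CPM in posterior cells, and low in both groups of mesoderm-like cells, at 0.819 and 0.680 CPM (interaction 4.09 ± 0.49, adjusted p = 0.000387). The zinc finger gene disco stood at 166.7 and 43.3 CPM in ectoderm and at 5.97 and 6.69 CPM in the mesoderm-like class (2.60 ± 0.44, adjusted p = 0.0064). Conversely, salm fell from 171.4 CPM in gnathal to 11.2 CPM in posterior cells of that class but lay at 232.7 and 168.8 CPM in ectoderm (-2.68 ± 0.28, adjusted p = 0.000117). Both genes were among the 10 leading genes of unnamed clusters of both libraries that also had ken and Abd-B there, with twi at 539.9 and 348.7 CPM, which the class leaves out. In a wider mesoderm class that holds them, the interaction was 3.86 for disco and -1.15 for salm, the latter not passing (adjusted p = 0.0601), so the difference of salm depends on the class chosen. For the POU gene nub the levels were 1.87 CPM in gnathal and 15.0 CPM in posterior mesoderm and 58.2 and 91.4 CPM in ectoderm (2.23 ± 0.33, adjusted p = 0.00237). For tsh they were 87.9 and 302.9 CPM in mesoderm and 16.7 and 299.0 CPM in ectoderm (-2.26 ± 0.17, adjusted p = 1e-05). Of 8054 genes 93 passed, 47 with a more positive and 46 with a more negative difference in mesoderm, 43 of them at least 2-fold, and all 93 had the same sign in both libraries. Calls numbered 2 without the library block, 5 with cells thinned to 3000 UMIs, 53 at resolution 2, 192 with a wider mesoderm class and 317 without the filter on low counts. Genes with a more positive difference included the inhibitor gene dnr1 (3.15 ± 0.33), cnc (3.09 ± 0.57, adjusted p = 0.0127), and the muscle genes Mlp60A (3.01), sls (2.69) and Act87E (2.49). Others were the growth factor gene Pvf3 (2.23 ± 0.20, adjusted p = 3.67e-05) and the rhodopsin gene Rh7 (2.13; by library 1.07 and 2.37). Mlp60A stood at 1.755 CPM in gnathal and 1.881 CPM in posterior mesoderm, and at 12.99 and 1.521 CPM in ectoderm. For sls the levels were 5.03 and 8.355 CPM in mesoderm and 9.173 and 3.193 CPM in ectoderm. The values of Mlp60A and sls therefore rest largely on the fall in ectoderm. Act87E rose in mesoderm, from 33.69 to 285.6 CPM, and stood at 5.242 and 8.576 CPM in ectoderm. Genes with a more negative difference in mesoderm included the secretory factor gene CrebA (-2.80 ± 0.46), the POU gene vvl (-2.72 ± 0.47), CG42260 (-2.77; by library -1.65 and -3.23) and CG12885 (-2.64). Further ones were Ect4, the fly SARM gene (-2.50 ± 0.24, adjusted p = 6.52e-05), the LIM homeobox gene tup (-2.41), prd (-2.24), dpp (-1.83 ± 0.22, adjusted p = 4e-04) and Blimp-1 (-1.60). In mesoderm CG12885 (5.03 and 5.03 CPM), CG42260 (12.05 and 11.07 CPM) and tup (5.26 and 5.51 CPM) hardly changed. Their values rest on the rise in ectoderm, where gnathal CG12885 and CG42260 had only 4 and 8 UMIs. CrebA, vvl, dpp and Blimp-1 fell in mesoderm and rose in ectoderm. CG1124 had 0 UMIs in gnathal against 78 in posterior mesoderm, at least 2.07-fold against a floor of 3 counts. Dop2R had 0 in gnathal against 46 in posterior ectoderm, at least 4.27-fold.

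**Figure D3:**
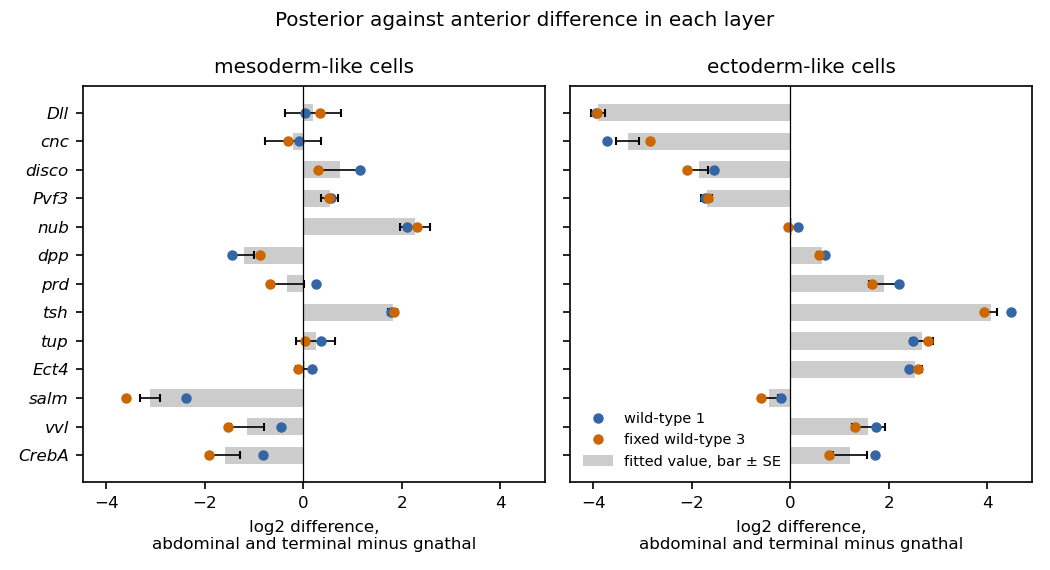
Log2 difference of posterior against gnathal cells (horizontal axes) for 13 genes in mesoderm-like (left) and ectoderm-like cells (right), as the fitted value (grey bar) with its standard error (line) and the value in each library (points). Dll and cnc lie near 0 in mesoderm and at -3.89 and -3.30 in ectoderm, while salm lies at -3.11 in mesoderm.

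By list, 3 of 13 gap genes had a more positive difference in mesoderm, among them pdm2 (1.17), and 0 a more negative one (6 adjusted over the list alone; camera adjusted p = 0.0698). Of 8 head and trunk regulators Dll and disco were more positive and tsh, salm (not passing with a wider mesoderm class) and hth (-0.46) more negative (5 adjusted over the list alone). The median of that list was -0.20 and its mean 0.28, and camera's direction was down (adjusted p = 0.00778, adjusted p = 0.126 with an estimated correlation). Of 10 segment polarity genes 1 passed, hh (0.57; 6 adjusted over the list alone; camera adjusted p = 0.00778, but 0.126 with an estimated correlation). Of 18 Notch genes 1 passed, Tom (-0.59; 10 alone; 2.94e-07), and of 8 EGF receptor genes 0 did (5 alone; 0.00375), but 0.126 for each with an estimated correlation. Of 9 pair-rule genes prd passed (3 adjusted over the list alone), and of 8 receptor genes trn passed (0.81; 1 adjusted over the list alone). None of the 9 FGF and 9 mesoderm subdivision genes passed over all genes, with 0 and 1 adjusted over the list alone. Camera called 4 of 17 lists, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, while fry called 0 and its mixed test 11.

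Mesoderm-like cells were divided by their UMIs of the cellularisation genes nullo, bnk, halo and slam, which are transcribed as the embryo forms cells. The purpose was to compare younger with older mesoderm, but whether the gate separates ages was not tested. At least 2 of their UMIs were found in 2.97% of mesoderm-like cells in wild-type 1 (86 cells) and 4.29% in the fixed library (149 cells). The shares were 29.1 and 32.2% of ectoderm-like and 50.6 and 50.4% of pole cell-like cells, at the median depths given above. The early-gated mesoderm share therefore lay below the share in both other classes, and cells with 0 such UMIs numbered 2502 and 2769. Early-gated cells were also deeper, with a median of 24678 against 21089 UMIs in wild-type 1 and 31659 against 24333 UMIs in the fixed library. Early-gated cells carried more sna, the zinc finger determinant of invaginating mesoderm (FBgn0003448, chromosome 2L, 15476593 to 15478260, minus strand; 1.74 ± 0.07, adjusted p = 1.61e-116), and more of the pair-rule gene eve (1.96). They also carried more of the midline and neurogenic genes sim (2.81; by library 1.62 and 3.42), rho (2.76; by library 1.49 and 3.49), vnd (2.48) and sog (1.78; by library 1.16 and 2.13), which are not genes of the mesoderm. They carried less of the visceral T-box gene org-1 (-1.31; by library -3.20 and -0.40) and of bap (-0.57; by library -1.08 and -0.20). Of 9237 genes 388 passed, 265 higher and 123 lower in early-gated cells, 71 at least 2-fold and 358 with the same sign in both libraries. This fit had 1 residual degree of freedom and assigned 1 common spread to all genes, so its p-values are very small. DESeq2 called 78, and without the library block edgeR called 0, with 126 at an unadjusted p under 0.05. With DESeq2's test 28 of the named results of this contrast lost their call and 13 kept it.

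Other genes higher in early-gated cells were CG14427 (3.60 ± 0.34), CG15480 (2.59; by library 1.44 and 2.93), and toc (1.84), with the PDZ protein gene bbg (1.83; by library 0.95 and 2.32) and ftz (1.83; by library 0.24 and 2.47). So was GAL4, named after its value was seen (1.26, adjusted p = 0.00025; by library 0.83 and 1.45). Lower genes were the Hox genes Dfd (-1.79; by library -6.55 and -1.41), Scr (-1.49; by library -0.42 and -2.38) and pb (4 UMIs in early-gated cells; -2.47). Others were CG34325 (-1.37; by library -0.64 and -2.0), CG2006 (-1.15; by library -1.72 and -0.91), AstA-R1 (-0.96, but 0.42 and not passing with a wider mesoderm class), the clock gene Clk (-0.94; by library -0.38 and -1.73) and bnl (-0.90; by library -1.69 and -0.49). CG31690 had 0 UMIs in early-gated and 220 in late cells, at least 4.66-fold lower against a floor of 3 counts over the early-gated group. Of 9 pair-rule genes 8 rose (8 adjusted over the list alone), among them prd, opa (0.99; by library 0.62 and 1.26) and run (1.16), with a camera adjusted p = 4.77e-49, but 0.63 with an estimated correlation. Of 18 Notch genes 9 rose and 1 fell (13 adjusted over the list alone; camera adjusted p = 3.55e-11, but 0.63 with an estimated correlation). Risers included E(spl)m8-HLH (0.82; by library 0.48 and 1.12), neur (0.63; by library 0.42 and 0.80) and E(spl)m2-BFM (0.70; by library 0.23 and 1.11). Of 8 EGF receptor genes rho and vn rose (1.09 for vn; by library 0.39 and 1.46) and pnt fell (-0.21; 6 adjusted over the list alone; camera adjusted p = 1.14e-08, but 0.63 with an estimated correlation). Of 8 receptor genes 6 rose (6 alone; 3e-08, but 0.63 as estimated), such as Tollo (0.84) and trn (0.33; by library -0.10 and 0.66). Of 13 gap genes 4 rose (8 alone; 7.43e-05, but 0.63 as estimated), such as knrl (0.93) and nub (0.81). Of 8 head and trunk regulators salm rose (1.11; by library -0.63 and 1.65; 4 alone; 0.0019, but 0.63 as estimated). Of 11 Wnt genes 2 rose and 1 fell (5 alone; 0.00184, but 0.642 as estimated), with wntD at 0.93 (by library 0.35 and 1.38) and Notum at -0.44. Of 6 JAK/STAT genes 0 passed (1 alone; camera 0.0269, but 0.63 as estimated). Camera called 8 of 18 lists with the preset correlation and 0 with an estimated one, where 0 had an unadjusted p under 0.05. On 1 residual degree of freedom the estimated version could call hardly any list, so that 0 does not decide. Fry called 0, in its mixed test too. Of 10 mesoderm subdivision genes 2 rose and 2 fell (6 alone; camera adjusted p = 0.063), with Him at -0.54 (by library -0.23 and -0.85). Of 11 segment polarity genes 3 rose (5 alone; camera adjusted p = 0.158), with hh at 0.55 (by library -0.14 and 0.91).

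The fixed and unfixed libraries were set side by side to describe what differs between preparations, with 1 library on each side and therefore no test. Over all cells used, the genes with the lowest ratio in the fixed library included several of muscle. Act57B, a muscle actin gene, stood at 81.1 CPM in wild-type 1 and 5.69 CPM in the fixed library (ratio 0.0702, 95% counting interval 0.0665 to 0.0740). The arginine kinase gene Argk (ratio 0.136), the troponin gene TpnC73F (0.173), the tubulin gene betaTub60D (0.179), the myosin light chain gene Mlc2 (0.275), the titin-like gene sls (0.285) and the nesprin gene Msp300 (0.303) followed. Others were CG5080 (0.250), CG33099 (0.276) and PPO1, a phenol oxidase gene of crystal cells (0.321). Clusters led by Mhc or TpnC73F held 4.71% of cells in wild-type 1 and 1.52% in the fixed library. Without those clusters the ratio rose to 0.717 for Mlc2 and 0.338 for TpnC73F, but was 0.132 for Argk and 0.0432 for Act57B. Another unnamed cluster in wild-type 1 (484 cells) had Act57B, Argk and betaTub60D among its leading genes. Higher in the fixed library were CG3961 (ratio 5.90, interval 5.58 to 6.24), Hsp70Bb (14.7 to 63.3 CPM, ratio 4.30, interval 4.12 to 4.50), lncRNA:CR45224 (3.63), snRNA:7SK (2.99) and drongo (2.54). They were followed by the neural factor gene SoxN (186.6 to 457.4 CPM, 2.45), Mnn1 (2.29), the chromatin gene Trl (2.28) and the EGF pathway gene S (2.28). Hsp70Bb belongs to a family of near-identical copies, so its separate level is uncertain. Of 2670 genes with at least 50 CPM in a library, 25 were at least 2-fold higher, 64 at least 2-fold lower and 2137 (80.0%) within 1.5-fold. The median log2 ratio was -0.20, and ribosomal protein genes held 37.9% of UMIs in wild-type 1 and 44.7% in the fixed library. After scaling by the median ratio, 87 genes were at least 2-fold higher and 29 lower.

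In mesoderm-like cells Hsp70Bb was again higher (ratio 4.84, interval 4.54 to 5.16), followed by the zinc finger gene MEP-1 (3.76), lncRNA:CR44206 (2.88), Trl (2.38), the growth regulator gene ex (2.24) and BtbVII (2.23). Lower were bnb (0.336), CG5028 (0.352), E(spl)m2-BFM (0.371), EloC (0.377), the calnexin gene Cnx99A (0.388), the transcription factor gene Myc (0.391) and capt, a regulator of actin (0.407). Of 2575 genes 21 were at least 2-fold higher and 39 lower, and 81.7% lay within 1.5-fold, around a median log2 ratio of -0.19. Relative to random lists of matched expression, mesoderm subdivision and muscle genes had a median log2 ratio of -0.82 over all cells, at percentile 0.04 of 10000 lists (-0.79 and 0.07 without the muscle-led clusters), and of -1.07 in mesoderm-like cells, below all 10000. In the latter, the cluster led by jeb and org-1 that stayed outside the class in the fixed library did not enter this value. Notch genes had a median of -0.46 over all cells (percentile 0.09) and -0.57 in mesoderm-like cells (percentile 0.01). Over all cells the median was 0.21 for ribosomal protein genes (above all 10000 random lists) and 0.31 for patterned receptor genes (percentile 99.6). It was 0.11 for Wnt genes (98.9), 0.10 for folding genes (98.2) and -0.38 for heat shock and stress genes (15.9).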

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

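The tests of the mix of early and late clusters, of depth in the bins, of free RNA in the muscle-led clusters and of late neuron genes without elav were chosen only after the result was seen.

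The posterior-against-gnathal difference differed between mesoderm-like and ectoderm-like cells for 93 genes, by a test of the difference itself. The log2 differences, mesoderm minus ectoderm, were 4.09 for Dll, 3.09 for cnc, 2.60 for disco, 2.23 for nub, 2.23 for Pvf3, -2.68 for salm, -2.26 for tsh, -2.50 for Ect4, -2.41 for tup, -2.24 for prd, -1.83 for dpp, -2.72 for vvl and -2.80 for CrebA. With a wider mesoderm class, salm was at -1.15 and did not pass (adjusted p = 0.0601). A different mix of early and late clusters in the bins stays open. With clusters led by sna or SNCF left out, 59.1% of the 93 genes still passed and all kept their sign, but that took no cell from the ectoderm of wild-type 1 (1225 cells), so the mix there stayed as it was. Cells of different depth or number stay open too, since after thinning every cell to 3000 UMIs only 5.06% of the called genes still tested passed, while 92.4% kept their sign. The loss of UMIs alone can end calls, so that test does not decide, and a layer-specific use of Hox-dependent regulators may also account for the genes but was not tested.

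Clusters led by late muscle genes such as TpnC73F, Mlc2 and Mhc held 4.71% of the cells of wild-type 1 (427 cells, exact 95% interval 4.29 to 5.17%) and 1.52% of the fixed library (190 cells, 1.31 to 1.75%), although the samples are labelled stage 5 to 10, before muscle forms. No test between classes of cells uses them, and they enter only the comparison of the libraries over all cells. An Mhc UMI was found in 79.4 and 65.8% of these cells, at 5149 and 6181.5 median UMIs, and in 7.54 and 4.77% of pole cell-like cells, at 18372.5 and 21858 median UMIs. By the bound set for this test, free RNA or doublets stay open. The pole cell share was 0.095 and 0.0725 of the share in these clusters, but the limits of these shares allow up to 0.143 and 0.119, past the bound set for this test, and the clusters were picked for such genes. Mhc stood at 1300 and 1203 CPM in them against 2.45 and 2.38 CPM in the other cells. Mlc2, which was not in the rule that picked them but was among their leading genes, stood at 2894 and 1878 against 9.42 and 6.75 CPM. For up the levels were 1225 and 897.6 against 2.25 and 1.54 CPM, and every muscle gene compared was higher there. Muscle genes were not held out of the clustering, so these values are not independent of how the clusters formed. Free RNA spread evenly over cells would not give such levels, so they argue against it alone for these genes. They do not decide on doublets with muscle cells, which would themselves need muscle cells in the sample. Such doublets are therefore no alternative to older embryos. That some embryos were older than labelled is a candidate explanation of its own, and it stays open. Counting cells with at least 5 UMIs over nSyb, brp, Syt1 and elav gave 2668 and 3617 cells. However, elav also passed in 38.9 and 39.6% of mesoderm-like cells, which voids that test. Without elav, 10 cells passed in wild-type 1 and 25 in the fixed library, on either side of the 20 set as a bound. At least 5 UMIs of the late fat body gene apolpp were found in 38 and 35 cells and of the late cuticle and tracheal genes kkv, serp and verm in 22 and 8 cells. The late glial genes repo, nrv2 and moody reached 5 UMIs in 704 and 1650 cells, but also in 3.18 and 7.74% of mesoderm-like cells. Wild-type 1 also held an unnamed cluster of 129 cells with apolpp at 1004 CPM and one of 163 cells led by Osi6, with serp at 143.6 and verm at 151.4 CPM. No bound was set for these values, so they do not decide.

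Early-gated mesoderm-like cells carried genes of neurogenic ectoderm and midline, such as sim, rho and vnd. RNA of early ectoderm cells, or doublets with them, may have added these transcripts, in which case genes far higher in early ectoderm should rise by a common share of the ectoderm level. Their median share was 3.69% in wild-type 1 (49 genes) and 4.57% in the fixed library (46 genes), with an upper quartile 6.08 and 2.81 times the lower one. These genes did not include sim, rho or vnd, which missed the limits on level or ratio. The largest shares in the fixed library were 41.5% for CG15480, 16.7% for sog and 15.2% for vn, and in wild-type 1 11.1% for Rgl. A common share allows under 3 in both libraries and another source needs over 3 in both, so this stays open. Median doublet scores were 0.0771 in early-gated against 0.0637 in late cells of wild-type 1 and 0.115 against 0.0992 in the fixed library, and no biological explanation was tested.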

How the results depend on the processing

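The wider mesoderm class, leaving out clusters led by sna or SNCF, leaving out clusters of few UMIs, and leaving out muscle-led clusters were tests chosen only after the result was seen. Of the 218 named gene results, 216 kept their direction and call with DESeq2's size factors, 216 without the filter, 216 without low-UMI clusters, 204 at resolution 2, 198 with the wider class, 192 with doublets kept and 186 with DESeq2's test, and all 112 axis results did with at least 2 UMIs in the winning bin. Thinning ended 68 calls of the 163 results it could test, Antp cells on the anterior side 29 of 112 and leaving out the sna- or SNCF-led clusters 20 of 177. Among the named results, DESeq2's losses fell mostly in the early contrast, where 28 lost their call and 13 kept it. Named results are the largest differences. Over all genes, DESeq2 kept only 1878 of the 3624 calls between the layers (51.8%).

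Thinning every cell to 3000 UMIs, which leaves fewer UMIs by construction, gave 1383 calls between the layers, 27 in the mesoderm contrast, 43 in the ectoderm contrast and 5 in the interaction. It turned run in mesoderm to -0.22 and ptc in ectoderm to 0.022. DESeq2's test gave 1878 calls between the layers and 78 for the early gate. Leaving out sna- or SNCF-led clusters gave 235 calls in the mesoderm contrast and Antp cells on the anterior side 222. The interaction had 317 calls without the filter, which tests more genes, 53 at resolution 2 and 192 with the wider class. The wider class turned ptc in the mesoderm contrast to 0.026 and AstA-R1 in the early contrast to 0.42. Except for thinning and the filter, the cause was not tested.

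Each comparison was paired within a library by the block, since both sides came from the same library, and the replicate numbers of the labels belong to differently named groups. Without the replicate block, 81 genes passed between the layers, 30 in the mesoderm contrast, 78 in the ectoderm contrast and 2 in the interaction. For the early gate edgeR then called 0, with 126 at an unadjusted p under 0.05. The library difference then counts as spread, by construction, and 150 of the 218 named results lost their call.

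Camera with an estimated correlation called 0 lists in every contrast, against 16, 3, 8, 4 and 8 with the preset one. For the layers and the early gate it rested on 1 residual degree of freedom and could call hardly any list. Lists at an unadjusted p under 0.05 then numbered 0, 1, 6, 4 and 0 in the order layer, mesoderm, ectoderm, interaction and early gate, and fry called 4, 1, 10, 0 and 0. With 1 library alone no residual degrees of freedom remain, so counts could not be recomputed. A named value counted as kept if it lay within 1 standard deviation, taken over the 2 libraries' values, of the fitted value. That held in 205 cases without wild-type 1 and in 181 without the fixed library. This bound is wider where the libraries disagree, and the fitted value comes from the same 2 libraries, so these counts do not measure agreement. In the early contrast the values without a library ranged from -0.14 to 0.91 for hh, -0.63 to 1.65 for salm and -0.10 to 0.66 for trn, negative without the fixed library.

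For the fixed against the unfixed library, scaling by the median ratio gave 87 genes higher and 29 lower, and leaving ribosomal protein genes out of the totals 66 higher. Leaving out the muscle-led clusters gave 24 higher and 56 lower, against 25 and 64. The mesoderm-like share of wild-type 1 was 22.9% with doublets kept, 28.6% with all barcodes and 25.3% at resolution 2, and that of the fixed library 26.6, 26.6 and 24.3%. The ectoderm-like share was 12.6% in wild-type 1 with doublets kept, and 20.4 and 20.3% in the fixed library with doublets kept and with all barcodes. The cause was not tested. An early gate of at least 4 UMIs and a thinned early gate left too few cells and gave no value.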

Other observations

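Mesoderm outside the named class included regional populations that appeared in both libraries. A cluster led by the caudal visceral mesoderm gene HLH54F with ken and Abd-B held 324 cells in wild-type 1, with Abd-B at 652.4 CPM and twi at 539.9 CPM, and a cluster led by ken and Abd-B held 427 cells in the fixed library, with Abd-B at 678.7 CPM and HLH54F at 41.3 CPM against 146.6 CPM in wild-type 1. Clusters led by the forkhead gene croc and by gt, a combination of the head, held 143 cells in wild-type 1 (croc 212.4 CPM, gt 379.4 CPM) and 129 in the fixed library (178.4 and 196.6 CPM). Crystal cell genes PPO1 and PPO2 led clusters of 88 and 127 cells. The myoblast factor gene lmd marked unnamed clusters of 586 cells (384.4 CPM) and 484 cells (672.3 CPM) in wild-type 1.

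Across mesodermal clusters mCD8GFP and its driver GAL4 followed no single order with twi. In wild-type 1 the sna-led cluster of 275 cells had twi at 794.6 CPM, GAL4 at 5.78 CPM and mCD8GFP at 74.3 CPM, while the cluster of 100 cells led by Alk and org-1 had twi at 110.6 CPM, a single GAL4 UMI and mCD8GFP at 244.2 CPM. In the fixed library the sna-led cluster of 729 cells had twi at 443.0 CPM, GAL4 at 7.39 CPM and mCD8GFP at 161.9 CPM, while the unnamed cluster of 1289 cells led by jeb and org-1 had twi at 127.5 CPM, GAL4 at 1.76 CPM and mCD8GFP at 320.8 CPM. There the SNCF-led cluster of 194 cells had twi at 347.2 CPM, GAL4 at 8.09 CPM and mCD8GFP at 68.4 CPM, against 398.2, 2.59 and 211.5 CPM in the cluster of 1309 cells led by tin. In the neurogenic ectoderm-like cluster led by rho mCD8GFP stood at 223.4 CPM. The neural gene SoxN was as high in head mesoderm and blood-like cells (646.7 and 1244 CPM) as in ectoderm-like cells (622.7 and 1284 CPM), against 26.5 and 44.5 CPM in mesoderm-like cells. The largest unnamed cluster of the fixed library held 1479 cells at a median of 1307 UMIs.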
